A study of Homo sapiens with 6 samples.

How the data were processed

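Poly(A)-selected RNA was sequenced from 6 libraries of H1, an established human embryonic stem cell line. Per the labels' protocols, the cells were kept undifferentiated on Matrigel in a hypoxic incubator, messenger RNA was isolated by its poly(A) tail, and libraries were made with a NEBNext Ultra RNA kit. The library titles give 3 groups of 2: the unedited line (wild type here) and 2 knockout lines named C5 and C45, in which TYW1 was disrupted. Replicate 2 of each group is the library whose title carries the suffix -2. Nothing in the labels says whether the 2 libraries of a line came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The running numbers in the titles were not used.

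The deposited table holds raw counts per gene, 1 column per library, with no normalization by the authors. FastQC 0.11.9, MultiQC 1.9, Trim Galore 0.6.5, STAR 2.7.4a and featureCounts 2.0.0 are listed with genome build hg38 per the submitters' processing notes, with no parameters or order. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Counts of overlapping and antisense genes can therefore share reads. Counts of genes with near-identical copies, such as TYW1 and TYW1B, the histone genes, the clustered protocadherins and many zinc finger genes, are uncertain for the same reason. Repeat families were not counted in the table. The only endogenous retroviral values here are those of annotated genes.

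The table has 60617 genes, identified by Ensembl number. Symbols were found for 60261 and coordinates, GC content and exon length for 58542 in GENCODE release 29, which uses the same build. A count was present in at least 1 library for 32700 genes. No entry lacked a gene identifier. After filterByExpr by group, 19254 genes were tested. Library totals ran from 29454061 to 40272558 counts. At 10 CPM (counts relative to the library total) the counting error alone is 4.98% to 5.83% of the value per library. No molecular identifiers were used, so the counting intervals and floors given here cover counting error only.

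Levels are CPM scaled by TMM factors, given as mean ± SD over libraries. Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test on raw counts, TMM, 3 groups in one fit, 3 residual degrees of freedom, median prior degrees of freedom 6.81, common biological coefficient of variation 26.3%). Every adjusted p of a gene is Benjamini-Hochberg adjusted over all genes tested, with a threshold of 0.05. The contrasts were the mean of both knockout lines minus wild type, each line minus wild type, and C45 minus C5. The p of the mean contrast does not include the spread between lines. Standard errors (SE) of log2 fold changes were obtained from the F statistic. A fold against a group with 0 counts was computed against a floor of 3 counts over the whole group. A ratio resting on 1 to 3 counts is given with its 95% counting interval.

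The 45 gene lists, the design, the alternatives and the rule for named genes were fixed before the data were examined. The rule names TYW1. It names the 12 largest rises and the 12 largest falls among genes called in both lines and in their mean, with average log2 CPM of at least 1, ranked by the smaller change of the lines. It also names up to 4 members of each list with the smallest p, all tested members of the tRNA-Phe and endogenous retroviral lists, and up to 3 members of lists that differ between lines. Some genes that the rule names are not reported here, though they count in their lists. No symbol of a list was unmatched. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. With an estimated correlation camera rests on the 3 residual degrees of freedom, so few lists can pass there whatever their correlation. Camera asks whether a list moves relative to other genes, and fry whether its members move on balance in one direction. Adjusted p values of lists are Benjamini-Hochberg adjusted over the lists.

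The test was also run on simulated counts, in 5 runs with 200 changed genes each. These counts used the libraries' own means and depths and the spread of each gene in the fit to the data. The changed genes all had a mean above 1 CPM, so recovery at lower levels was not measured. For knockout against wild type (18543 genes tested) it recovered 90.2% of 4-fold and 39.8% of 2-fold changes, with a mean of 8.2 false calls. For C45 against C5 (18493 genes tested) it recovered 87.4% and 27.0%. In knockout against wild type 4490 genes were called in the data, many more than the 200 changed in simulation. Fewer changed genes make the adjusted threshold stricter, so recovery in that contrast of the data may be higher. No pair of libraries agreed within sampling noise. Alternatives were other scalings, DESeq2 1.42.0, limma voom, other low-count filters, other groupings of libraries, minimum fold changes, a replicate term and leaving out each library. Leaving out a library also lowers the residual degrees of freedom, so a call or count lost there can reflect lower power and not a changed level. A correction for GC content and exon length, which were known for 98.7% of tested genes, and a test of the phenylalanine tRNA list without TYW1 were added after seeing the data.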

Results

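RNA was sequenced from undifferentiated H1 human embryonic stem cells with and without TYW1, an iron-sulfur enzyme that makes the tricyclic base from which wybutosine, a modified guanosine beside the anticodon of phenylalanine tRNA, is built. The study asks what loss of this modification does in neuronal differentiation and to endogenous retroviruses of the HERV-K family. There were 2 libraries each of wild type, knockout line C5 and knockout line C45. Replicates 1 and 2 held 37137860 and 29454061 counts in wild type, 40272558 and 37767666 in C5, and 29547521 and 39967929 in C45.

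TYW1 messenger RNA was 8.14-fold lower in the knockout lines. The gene (ENSG00000198874, chromosome 7, 66995173 to 67239519, plus strand, hg38) stood at 38.6 and 34.3 CPM in the wild-type libraries. It stood at 2.91 and 4.31 CPM in C5 and at 3.75 and 7.32 CPM in C45. The means were 36.5 ± 3.05 CPM (SD, n = 2) and 4.57 ± 1.92 CPM (SD, n = 4), a log2 fold change of -3.03 (SE 0.28, adjusted p = 0.00038). Its near-identical copy TYW1B had 3.75 ± 0.692 CPM (n = 2) and 6.51 ± 1.87 CPM (n = 4), a log2 difference of 0.78 that did not pass (adjusted p = 0.119).

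Of 10 tested genes that modify phenylalanine tRNA, TYW1 included, 4 fell and none rose (also 4 adjusted over the list alone): TYW1; TRMT12, which acts on the product of TYW1, 3.15-fold; TYW3, the next methyltransferase of the pathway, 1.82-fold; and LCMT2, which performs the last steps, 3.16-fold. TRMT5, TYW5, FTSJ1, THADA and WDR6 had log2 differences of -0.06, 0.37, -0.26, -0.30 and -0.45 and did not pass. The whole list stood lower by camera (adjusted p = 0.0155; adjusted p = 0.522 with an estimated correlation) and by fry (0.0127). Without TYW1, a test added after seeing the data, 3 of the 9 others fell (also 3 adjusted over the list alone), and they did not pass camera (adjusted p = 0.0726; adjusted p = 0.530 with an estimated correlation) and passed fry (0.0330). Without wild-type replicate 2 the count was 2, with LCMT2 at adjusted p = 0.069 and TYW3 at 0.0518, and TYW3 also missed the threshold without C5 replicate 2 (0.0629). Without C45 replicate 1, FTSJ1 (0.0435) and WDR6 (0.0139) passed, and LCMT2 was at log2 -2.33 in place of -1.66. WDR6 also passed with no low-count filter (adjusted p = 0.026), with correction for GC content and length (0.0184) and with line as a random block (0.0101). In the last of these fits a negative consensus correlation within lines (-0.36) lowers the estimated error, so its passes here and below are lenient. Of 12 genes near TYW1 on chromosome 7, AUTS2 fell 2.08-fold and KCTD7 rose 2.15-fold (also 1 and 1 adjusted over the list alone). The KCTD7 call was lost without wild-type replicate 1 (adjusted p = 0.152), wild-type replicate 2 (0.0874) or C5 replicate 2 (0.0512), and 2 genes fell without C45 replicate 1. This neighbouring list had a median log2 of -0.24 and did not pass camera (adjusted p = 0.228), and passed fry (0.0127).

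**Figure D1:**
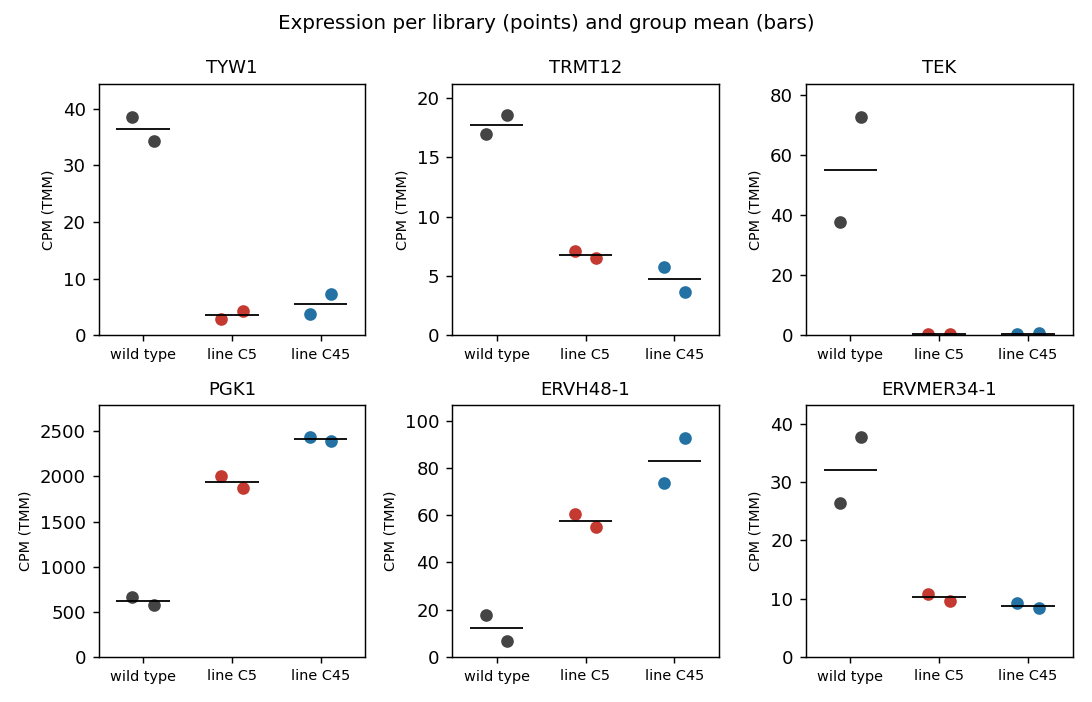
CPM after TMM scaling (vertical axes, linear, from 0) of 6 genes in each library (points) of wild type, line C5 and line C45, with group means as bars. TYW1 lay at 34.3 and 38.6 CPM in wild type and at most at 7.32 CPM in the knockout libraries.

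Wild-type and knockout libraries separated on the first principal component, which held 60.2% of the variance (wild type -83.0 and -115, knockout 30.5 to 75.5). Across genes, libraries of the same line correlated at 0.970 in wild type, 0.983 in C5 and 0.967 in C45. Correlations were 0.965 to 0.982 between C5 and C45 libraries, and 0.900 to 0.956 between wild-type and knockout libraries (Pearson's r of log2 CPM across genes, which are not independent replicates). The wild-type pair itself differed at single genes. TSHZ1, a zinc finger homeobox gene, and DOK6, PTGR3, ZNF516 and NFATC1 on distal 18q were lower in replicate 2 than in replicate 1, and 7 of 29 expressed genes of that segment were lower by more than 1 log2 unit. The knockout lines differed there too, with 13 of the 29 called higher and 3 lower than in wild type. Among all tested genes 23.3% were called. The mitochondrially encoded share of counts was 3.24% and 3.29% in wild type, 2.703% and 2.492% in C5, and 1.83% and 2.47% in C45.

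**Figure D2:**
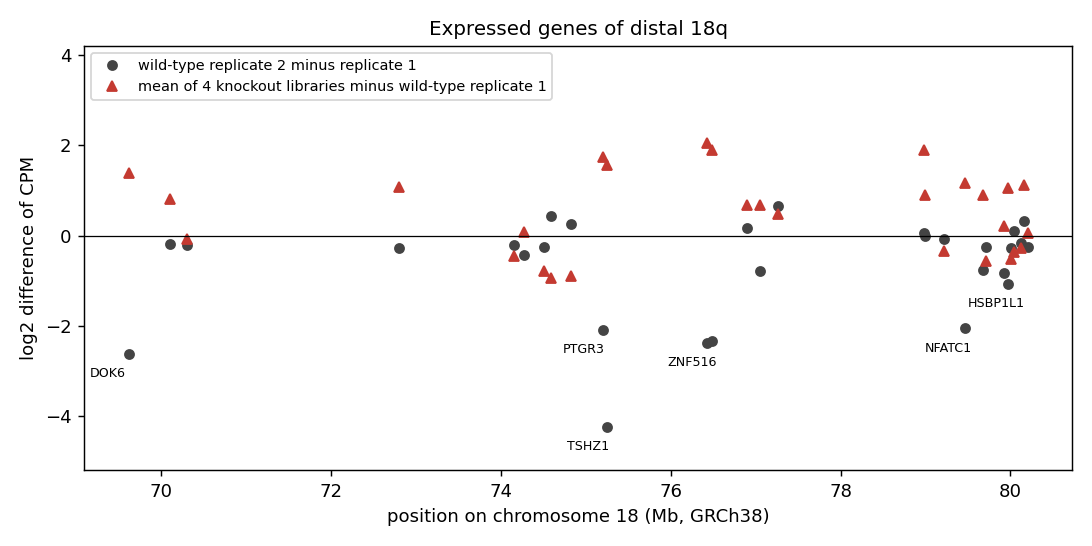
Log2 difference of CPM from wild-type replicate 1 (vertical axis) for 29 expressed genes along chromosome 18 (horizontal axis, Mb), for wild-type replicate 2 (circles) and the mean of the 4 knockout libraries (triangles). Genes more than 1 log2 unit lower in replicate 2 are named except the antisense gene beside ZNF516, and 18 genes lie within 0.5 of 0.

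Among the 12 largest rises in both knockout lines were LHX1, a homeobox regulator of gastrulation (0.401 ± 0.283 CPM in wild type, n = 2, and 19.5 ± 12.3 CPM in knockout, n = 4; log2 5.32), and SOX1, an early marker of neuroectoderm (0.597 ± 0.654 and 17.6 ± 2.33 CPM; 28.4-fold). HES4, a Notch-related repressor, rose 34.1-fold, FOXC1, a mesodermal forkhead factor, 26.2-fold, the phosphatase gene PTPRB 23.0-fold, OLIG1 22.0-fold and NDNF 19.8-fold. ANXA2R, TBX5, BMP3, OVGP1 and LINGO3 completed the 12, rising 28.4-fold to 49.8-fold. TEK, which encodes the angiopoietin receptor, fell 117-fold (55.2 ± 24.7 to 0.462 ± 0.0851 CPM), VAT1L 77.8-fold, the carbonyl reductase gene CBR1 by 6.32 on the log2 scale and ZNF300 58.4-fold. Several of these folds depended on single libraries. Without wild-type replicate 2 the log2 change was 4.74 for ANXA2R, 4.49 for TBX5, 4.57 for BMP3, 3.89 for LINGO3, 4.01 for SOX1, 3.67 for OLIG1, 3.93 for PTPRB, 3.76 for FOXC1 and -5.17 for ZNF300. Without wild-type replicate 1 LHX1, SOX1, OLIG1, PTPRB and NDNF were at 6.30, 6.95, 6.46, 5.46 and 4.98, FOXC1 rose 339-fold, and ANXA2R, TBX5, BMP3 and LINGO3 had no wild-type count left. BMP3 was at 4.51 and CBR1 at -9.34 without C45 replicate 2, VAT1L at -7.25 without C5 replicate 1, and HES4 at 4.31 with correction for GC content and length.

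ZNF680 and PPP1R17 had 0 counts in all 4 knockout libraries, which makes them at least 524-fold and at least 294-fold lower. ZNF248 had 2 counts there, a ratio of 428 (counting interval 118 to 3551), with a fitted log2 change of -9.13 that was -8.34 without wild-type replicate 2. Both counts lay in C45 replicate 2, so these fitted values depend on the prior count. Without that library no knockout count is left and no fold is given. HTR1A, HDX, ZNF229, ZNF736 and ZNF37A were the other members of the 12 largest falls. Among knockout libraries HDX, ZNF736 and ZNF37A had counts only in C45 replicate 2, so their fitted log2 changes also depend on the prior count. The means of ZNF736 were 6.05 CPM in wild type and 0.0503 CPM in knockout. ZNF736 and ZNF680 are neighbours on chromosome 7 (64307459 to 64354860 and 64519884 to 64563106, hg38), which also carries TYW1. Of 56 called genes with at least 1 CPM in wild type and at least 20-fold less in knockout, 7 (12.5%) carry ZNF names. Among all tested genes, which were not chosen by level, 2.82% do, so the 2 shares are not matched. The neighbours ZNF736 and ZNF680 are among the 7. Of the 56, 12 were less than 20-fold lower in either C5 or C45. Another 38 genes were at least 20-fold higher. Without wild-type replicate 2 the calls of BMP3 (log2 4.57, adjusted p = 0.0574) and ZNF736 (log2 -4.42 in place of -8.24, adjusted p = 0.171) were lost, and limma voom also lost both (0.091 and 0.0621).

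By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2336 genes rose and 2154 fell in knockout against wild type, 23.3% of those tested. Of these, 1699 and 1168 changed at least 2-fold. The total of 4490 became 2927 without wild-type replicate 1, 1924 without wild-type replicate 2, 2977 without C5 replicate 1 and 2488 without C5 replicate 2. Of the 4490, 2542, 1816, 2883 and 2460 were still called there, none with the opposite sign. Correction for GC content and length, added after seeing the data, gave 2419 higher and 3292 lower.

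Most of the hypoxia-responsive and glycolytic genes tested rose. Of 24 tested, 18 rose and 1 fell (19 and 1 adjusted over the list alone), with a median log2 change of 1.03. BNIP3, a mitophagy receptor, rose 7.40-fold (62.8 ± 16.6 CPM, n = 2, to 466 ± 57.8 CPM, n = 4). The glycolytic genes PGK1 (3.49-fold), LDHA (2.46-fold) and PFKFB4 (3.04-fold) rose as well. ADM, named after its values were seen, was the member that fell (log2 -1.39), and the falls were 0 without wild-type replicate 2 (ADM at log2 -0.59, adjusted p = 0.132) and 2 without C45 replicate 1. Transcripts encoded by mitochondrial DNA fell, 10 of 13 with none higher (12 and none adjusted over the list alone), with a median log2 change of -0.76. MT-CYB fell 2.44-fold, MT-ATP6 2.05-fold, MT-CO3 2.02-fold and MT-CO2 1.92-fold. These are the messenger RNAs. The mitochondrial ribosomal RNAs made up 0.293% and 0.349% of counts in wild type, 0.467% and 0.578% in C5, and 0.329% and 0.772% in C45. Of 24 nuclear-encoded respiratory chain genes, 0 were called by edgeR, also adjusted over the list alone, and NDUFV1 had the smallest p (log2 0.39, adjusted p = 0.0821; with total-count scaling 0.0397). In this list 1 gene rose without C45 replicate 1. Camera placed the hypoxia list higher (adjusted p = 3.09e-10; 0.353 with an estimated correlation) and the mitochondrial list lower (adjusted p = 4.12e-08; 0.530 with an estimated correlation). Fry gave adjusted p = 0.0114 and 0.035.

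Among targets of ATF4, the transcription factor of the integrated stress response, 10 of 24 fell and 1 rose (also 10 and 1 adjusted over the list alone). The cystine transporter SLC7A11 fell 9.40-fold (70.9 ± 11.5 to 8.0 ± 3.15 CPM), ATF5 8.24-fold, the amino acid transporter SLC7A5 4.71-fold and the serine synthesis enzyme PSAT1 2.15-fold. DDIT4, which is also induced in hypoxia and was named after its values were seen, rose (log2 2.13; 1.37 and 3.56 without wild-type replicates 1 and 2), and 2 members rose without C45 replicate 2. Of 20 aminoacyl-tRNA synthetases 9 fell and 1 rose (10 and 2 adjusted over the list alone), with WARS1 2.53-fold and TARS1 2.07-fold lower. Of 29 genes for other tRNA modifications 10 fell and 1 rose (11 and 1 adjusted over the list alone), including METTL1 4.07-fold, TRMT61A 3.24-fold, ALKBH8 3.06-fold and PUS1 2.06-fold. ADAT2, named after its values were seen, rose (log2 1.07), except without either wild-type replicate or C5 replicate 2. The 3 lists stood lower by camera (adjusted p = 0.00298, 0.00141 and 0.000211), which with an estimated correlation became adjusted p = 0.543, 0.543 and 0.522. The ATF4 count of 10 was 5 without wild-type replicate 2 and 6 without C5 replicate 2. The synthetase count of 9 was 4 without either wild-type replicate, 5 without C5 replicate 1 and 3 without C5 replicate 2, and its 1 rise was lost without any one of these 4 libraries.

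In the unfolded protein response list 7 of 16 fell and 1 rose (also 7 and 1 adjusted over the list alone). HSPA5, the main chaperone of the endoplasmic reticulum, fell 1.93-fold and CALR 1.80-fold, while EDEM1, a degradation factor, rose 2.33-fold. Camera gave adjusted p = 0.0154, and 0.543 with an estimated correlation. The count of 7 was 4 without wild-type replicate 1, wild-type replicate 2 or C5 replicate 1 and 3 without C5 replicate 2, and the EDEM1 call was lost without wild-type replicate 2 (adjusted p = 0.063). Of 12 heat shock genes 4 fell and none rose (also 4 adjusted over the list alone): HSPA8 2.71-fold, DNAJA1 2.35-fold, HSPH1 1.79-fold and CRYAB 13.2-fold; the list did not pass camera (adjusted p = 0.0857). Among 32 ribosomal protein genes 3 rose, including RPL3 (1.35-fold) and RPL7A (1.36-fold), and none fell. None passed adjusted over the list alone. Camera gave adjusted p = 0.00298, and 0.543 with an estimated correlation. This count of 3 was 1 without wild-type replicate 1 and 0 without wild-type replicate 2, C5 replicate 1 or C5 replicate 2, and it was 1 with DESeq2 size factors (RPL3 at adjusted p = 0.0506) and 8 with total counts. DESeq2's own test called neither RPL3 (0.0975) nor RPL7A (0.0578), and RPL7A also missed the threshold with correction for GC content and length (0.0823). Of 21 genes of ribosome quality control and nonsense-mediated decay, MAP3K20, a sensor of ribosome collisions, and GTPBP1 rose 2.07-fold and 1.49-fold and SMG5 fell 1.49-fold (also 2 and 1 adjusted over the list alone; camera adjusted p = 0.22). The SMG5 and GTPBP1 calls were lost without wild-type replicate 1 (adjusted p = 0.0662 and 0.123), wild-type replicate 2 (0.0600 and 0.0972), C5 replicate 1 (0.0644 and 0.0847) or C5 replicate 2 (0.103 and 0.0915), MAP3K20 was lost without wild-type replicate 2 (0.0858), and the fallen were 6 without C45 replicate 1, 2 without C45 replicate 2 and 8 with correction for GC content and length.

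Annotated endogenous retroviral genes went in both directions. ERVH48-1, which encodes suppressyn, an inhibitor of syncytin-mediated fusion, rose 5.64-fold (12.2 ± 7.71 CPM, n = 2, to 70.4 ± 16.7 CPM, n = 4). ERVMER34-1 fell 3.39-fold (32.1 ± 8.01 to 9.49 ± 1.02 CPM). The HERV-K transcript ERVK13-1 fell 2.26-fold (3.83 ± 1.04 to 1.70 ± 0.178 CPM). ERVK3-1 (2.87 ± 0.158 and 1.75 ± 0.456 CPM, log2 -0.71, adjusted p = 0.201) and ERV3-1 (log2 0.25, adjusted p = 0.612) did not pass, though ERVK3-1 passed with line as a random block (log2 -0.75, adjusted p = 0.0446). That fit is lenient because of its negative correlation within lines (-0.36), and it called 4131 genes higher and 3984 lower. The count of 1 higher and 2 lower of 5 was the same adjusted over the list alone, and camera did not pass (adjusted p = 0.501). The ERVK13-1 call was lost without wild-type replicate 2 (adjusted p = 0.194), C5 replicate 1 (0.0929) or C5 replicate 2 (0.11), and ERVH48-1 was at log2 3.31 without wild-type replicate 1. Of 6 pluripotency RNAs linked to HERV-H, ABHD12B rose 2.95-fold and LINC-ROR fell 8.14-fold (1 and 2 adjusted over the list alone; camera adjusted p = 0.29). The first call was lost without wild-type replicate 2 (adjusted p = 0.111) and the second without wild-type replicate 1 (0.0819), where ABHD12B was at log2 2.28 in place of 1.56. Without C45 replicate 1 LINC-ROR was at log2 -3.93 in place of -3.02 and 2 fell, as 2 did with correction for GC content and length.

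Genes that silence retroelements included large falls. DNMT3B, a de novo DNA methyltransferase, fell 2.83-fold (3101 ± 7.67 to 1111 ± 302 CPM), UHRF1, which directs maintenance methylation, 3.54-fold, and DNMT1 1.53-fold, while ATF7IP rose 1.51-fold. CBX5, named after its values were seen, was the other rise (log2 0.56). In that list 6 of 27 fell and 2 rose (the same adjusted over the list alone), and camera did not pass (adjusted p = 0.138). The 6 became 3 without wild-type replicate 1, 2 without wild-type replicate 2, C5 replicate 1 or C5 replicate 2, and 11 without C45 replicate 1. DNMT1 missed the threshold without wild-type replicate 2 (adjusted p = 0.0668), C5 replicate 1 (0.069) or C5 replicate 2 (0.0577), and no rise in the list held when any one of the wild-type or C5 libraries was left out. Among 543 genes with ZNF names 63 fell and 45 rose (60 and 38 adjusted over the list alone), and ZNF562 fell 15.9-fold. Camera gave adjusted p = 0.27. For the same 543 genes these counts were 44 and 27 without wild-type replicate 1, 26 and 18 without wild-type replicate 2, 40 and 26 without C5 replicate 1, 33 and 26 without C5 replicate 2, and 105 and 66 without C45 replicate 1.

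Several pluripotency genes fell, among them DNMT3B and ZFP42. POU5F1 and SOX2, given here after their values were seen, did not pass (2140 ± 404 and 2808 ± 228 CPM, adjusted p = 0.0667; 275 ± 25.1 and 213 ± 25.8 CPM, adjusted p = 0.119). POU5F1 passed, higher in knockout, with total counts (adjusted p = 0.0208), limma voom (0.0405), correction for GC content and length (0.043), line as a random block (0.0088) and without wild-type replicate 1 (0.0294). SOX2 passed, lower, with line as a random block (0.0167) and without C45 replicate 2 (0.0385). In the core list 10 of 21 fell and 3 rose (11 and 4 adjusted over the list alone). Besides DNMT3B, ZFP42 fell 3.06-fold, L1TD1 2.31-fold and USP44 2.17-fold, and NANOG, DPPA2 and UTF1, named after their values were seen, rose (log2 0.80, 1.26 and 2.44). Camera placed the list lower (adjusted p = 0.0168; 0.522 with an estimated correlation). The 10 became 5 without wild-type replicate 2 or C5 replicate 2 and 6 without C5 replicate 1, and the 3 became 1 without wild-type replicate 2 (NANOG at adjusted p = 0.201, DPPA2 at 0.128). NANOG also missed the threshold without C5 replicate 1 (0.0611), and UTF1 without either C45 library (0.051 and 0.0528), by DESeq2 (0.0719) and with correction for GC content and length (log2 1.56, 0.116). UTF1 was at log2 5.15 and 1.52 without wild-type replicates 1 and 2. Of 12 markers of naive pluripotency ESRRB rose 8.72-fold, TFAP2C 10.8-fold and DPPA5 fell 9.49-fold (4 and 1 adjusted over the list alone; camera adjusted p = 0.0726). DPPA5 missed the threshold without wild-type replicate 1 (adjusted p = 0.191), wild-type replicate 2 (0.106), C5 replicate 2 (0.0964) or C45 replicate 2 (0.0778) and with 2 genotype groups (log2 -2.63, adjusted p = 0.0771), and was at log2 -4.26 and -4.93 in place of -3.25 without C5 replicate 1 and C45 replicate 1. TFAP2C was at log2 6.11 and 2.53 in place of 3.43 without wild-type replicates 1 and 2. The naive rises were 6 without wild-type replicate 1. Of 13 primed markers 5 rose and 4 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.732). DUSP6 rose 2.61-fold, and OTX2 and VCAN fell 2.66-fold and 2.13-fold. Besides THY1, further calls, named after their values were seen, included rises of ZIC2 and SALL1 and falls of CD24 and CYTL1. THY1 missed the threshold without wild-type replicate 2 (adjusted p = 0.0696), as did SALL1 (0.109), CD24 (0.0533) and CYTL1 (0.0594), ZIC2 without wild-type replicate 1 (0.165), and ZIC2 (0.0537) and CD24 (0.0606) without C5 replicate 2. The primed counts were 2 and 2 without wild-type replicate 2, and the rises were 3 without wild-type replicate 1 or C5 replicate 2.

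Neural genes went both ways in these undifferentiated cells. Of 20 neural progenitor genes 7 rose and 5 fell (8 and 5 adjusted over the list alone). SOX1 and LMO3 (3.40-fold) rose, and OTX2 and FABP7, a radial glia gene, fell (2.66-fold and 5.43-fold). The other falls, named after their values were seen, were OTX1, LHX2 and DACH1. Of 22 neuronal genes 4 rose and 4 fell (4 and 6 adjusted over the list alone). ONECUT1 (7.12-fold) and NEFL, a neurofilament gene (3.79-fold), rose, and MAP2 (3.10-fold) and SYP, a synaptic vesicle gene (4.40-fold), fell. STMN2 and GAD1 rose and DCX and SYN1 fell, all named after their values were seen. Among 28 axon guidance genes 8 rose and 5 fell (9 and 6 adjusted over the list alone), with ROBO2 4.72-fold and NTN4 3.67-fold higher. The falls were SEMA3A and, named after their values were seen, SEMA3D, SEMA6D, UNC5D and NRP1. SEMA3A missed the threshold without wild-type replicate 2 (adjusted p = 0.0674). None of the 3 lists passed camera (adjusted p = 0.228, 0.55 and 0.501). The fallen neural progenitor genes were 2 without wild-type replicate 2 and 3 without wild-type replicate 1, C5 replicate 1 or C45 replicate 2. The axon guidance counts were 2 and 1 without wild-type replicate 2, and the fallen were 3, 2 and 2 without wild-type replicate 1, C5 replicate 1 and C5 replicate 2. Of the genes of this paragraph named after their values were seen, each but STMN2 and DCX missed the threshold when at least 1 of the libraries was left out, DACH1 with any of them (adjusted p = 0.0531 to 0.166). DACH1 also missed it with 2 genotype groups (0.136) and by DESeq2 (0.0512), GAD1 by limma voom (0.0773), and SEMA6D by limma voom (0.0507) and with total counts (0.0582). Without wild-type replicates 1 and 2 the log2 change of SOX1 was 6.95 and 4.01 in place of 4.83 and that of ROBO2 3.27 and 1.61 in place of 2.24, and NEFL was at 2.54 in place of 1.92 without replicate 1.

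Some markers of other cell types that a stem cell culture could hold changed. Of 8 fibroblast and mesenchymal genes 4 fell and none rose (also 4 adjusted over the list alone), among them the collagen gene COL1A1 (141 ± 5.30 to 28.9 ± 3.28 CPM, 4.87-fold), S100A4 (2.43-fold), TAGLN (121 ± 48.7 to 10.5 ± 3.08 CPM, 11.5-fold) and PDGFRB (2.6-fold). The list stood lower by camera (adjusted p = 0.00298; 0.522 with an estimated correlation) and by fry (0.0127). Of 11 mesendoderm and mesoderm genes 5 rose and 1 fell (6 and 2 adjusted over the list alone), with rises of LHX1, GSC (17.5-fold), TBX6 (3.63-fold), MESP1 (4.57-fold) and, named after its values were seen, MESP2, and with KDR, named likewise, lower (log2 -0.95). Of 8 endoderm genes AFP (4.73 ± 2.48 to 0.0249 ± 0.0288 CPM), CER1 and APOA1 fell and FOXA1, named after its values were seen, and HHEX rose (4 and 2 adjusted over the list alone). Of 7 neural crest genes NGFR (3.46-fold) and SOX9 (1.83-fold) rose and none fell (also 2 adjusted over the list alone). Of 5 trophoblast and amnion genes GATA2 (6.81-fold) and GABRP (3.74-fold) rose and IGFBP3 fell 5.58-fold (also 2 and 1 adjusted over the list alone). The last 4 lists did not pass camera (adjusted p = 0.29, 0.479, 0.361 and 0.847). Without wild-type replicates 1 and 2 the log2 change was 6.86 and 3.25 for GSC and 5.11 and 1.91 for GATA2, in place of 4.13 and 2.77. LHX1 was at 6.30 without replicate 1, and TBX6 at 2.47, IGFBP3 at -1.87 and AFP at -7.82 without replicate 2, in place of 5.32, 1.86, -2.48 and -8.43.

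Some marker calls were lost when a library was left out, where power is also lower. A lost call is thus not by itself a changed level. S100A4 was at log2 -1.26 and -1.37 without wild-type replicates 1 and 2. It was at -1.22 and -1.34 without C5 replicates 1 and 2, and at -1.28 with all libraries. The mesendoderm rises were 3 without wild-type replicate 2 or C5 replicate 2, and the falls 0 without wild-type replicate 1 or C5 replicate 2. MESP1 missed the threshold without wild-type replicate 1 (adjusted p = 0.0666), wild-type replicate 2 (0.102) or C5 replicate 2 (0.0773). S100A4 missed it without any one of the wild-type and C5 libraries (0.0527 to 0.0688). The fallen endoderm genes were 1 without wild-type replicate 1, C5 replicate 2 or C45 replicate 2, where CER1 had adjusted p = 0.423, 0.0967 and 0.0531 and APOA1 0.0924, 0.161 and 0.0908. APOA1 also missed the threshold without wild-type replicate 2 (0.316) or C5 replicate 1 (0.155). No endoderm rise held without C45 replicate 2 (HHEX at adjusted p = 0.0599), and DESeq2 called none of APOA1 (0.0616), HHEX (0.0841) and FOXA1 (0.118). Without wild-type replicates 1 and 2 CER1 was at log2 -1.45 and -3.18, HHEX at 5.41 and 1.52 and FOXA1 at 7.42 and 1.85, and APOA1 was at -2.47 without replicate 2 and -3.70 without C45 replicate 1. MESP2 missed the threshold by limma voom (adjusted p = 0.0521) and without any one of the wild-type and C5 libraries (0.0689 to 0.160). SOX9 missed the threshold without wild-type replicate 1 (adjusted p = 0.141), wild-type replicate 2 (0.164), C5 replicate 1 (0.052), C5 replicate 2 (0.136) or C45 replicate 2 (0.050), where 1 neural crest gene fell, and GABRP without wild-type replicate 2 (0.0609).

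Of 17 replication genes 9 fell and none rose (11 and none adjusted over the list alone), including UHRF1, MCM5 of the replicative helicase (2.24-fold), CDC6 (2.20-fold) and RRM2 of ribonucleotide reductase (1.92-fold). Of 19 mitotic genes HMGB2 rose 1.58-fold and none fell (also 1 adjusted over the list alone; camera adjusted p = 0.479). Among 10 histone genes 5 fell and 1 rose (7 and 1 adjusted over the list alone), with H2AC6 5.11-fold and H2BC12 3.31-fold lower, besides H4C8 and, named after their values were seen, H2BC5 and H3C1. Because most replication-dependent histone transcripts lack poly(A) tails, these libraries hold only their tailed share. Of 25 p53 target genes 12 rose and 1 fell (15 and 1 adjusted over the list alone). GDF15 rose 8.01-fold, BTG2 7.52-fold and the cell cycle inhibitor gene CDKN1A 3.93-fold, and TP53I3 fell 2.29-fold. Against wild type 5 p53 targets rose in C5 and 15 in C45, while none of the 25 was called in C45 against C5 over all genes. Camera gave adjusted p = 8.94e-06 for replication, 0.0231 for histones and 0.00124 for p53 targets, and with an estimated correlation adjusted p = 0.543, 0.543 and 0.530. The replication count was 5 and the histone count 2 without wild-type replicate 1 (H4C8 at log2 -1.81 in place of -2.60, adjusted p = 0.0521, H2BC5 at 0.0676 and H3C1 at 0.396), where H2AC6 was at log2 -1.54 in place of -2.35, and the p53 count was 7 without wild-type replicate 2. HMGB2 missed the threshold without wild-type replicate 2 (adjusted p = 0.121) or C5 replicate 2 (0.0539), 3 mitotic genes rose without C45 replicate 1, and GDF15 missed it with line as a random block (0.0538). H3C1 missed it without any library but C45 replicate 2.

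**Figure D3:**
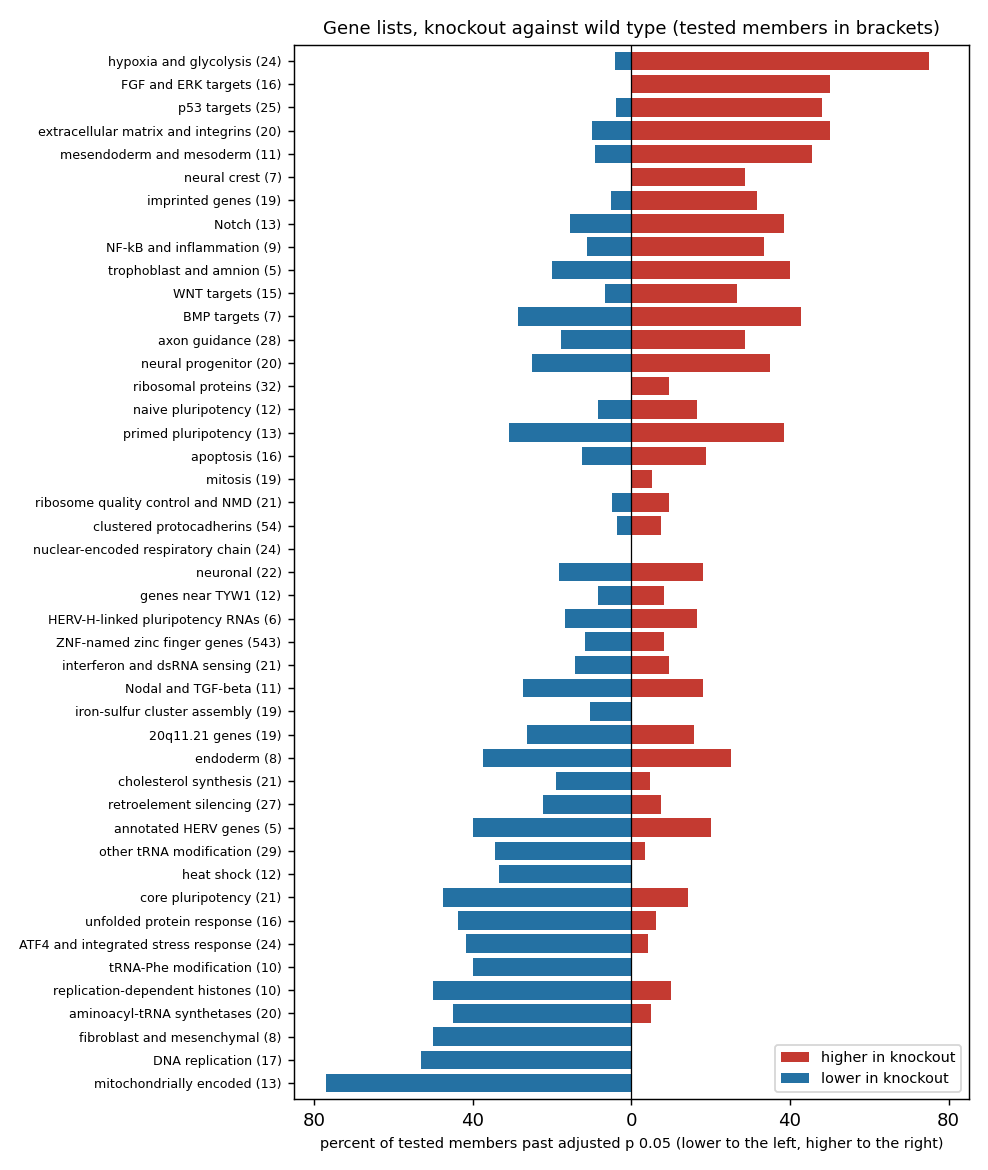
Percent of tested members of each of 45 gene lists (tested number in brackets) that passed an adjusted p of 0.05 in knockout against wild type, lower to the left and higher to the right. Hypoxia and glycolysis genes had 18 of 24 members higher, and mitochondrially encoded genes 10 of 13 lower.

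In line C5 BNIP3 rose against wild type (437 CPM in C5, mean of n = 2, and 62.8 ± 16.6 CPM in wild type), as did PGK1 (log2 1.64) and SOX1 (log2 4.68), and SLC7A11 and COL1A1 fell (log2 -2.74 and -2.26). TYW1 was 10.1-fold lower (adjusted p = 0.00208). Here 16 of 24 hypoxia and glycolysis genes rose (17 adjusted over the list alone) and 7 of 13 mitochondrially encoded genes fell (9 adjusted over the list alone). SOX1 was at log2 6.81 and 3.87 without wild-type replicates 1 and 2. Camera gave adjusted p = 1.26e-10 and 3.71e-07 for these lists, and with an estimated correlation adjusted p = 0.338 and 0.533. Of 25 p53 targets 5 rose and 1 fell (7 and 1 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0503) or fry (0.281). The hypoxia rises were 7 without wild-type replicate 1, 8 without wild-type replicate 2, 6 without C5 replicate 1 and 8 without C5 replicate 2. The mitochondrial falls were 1, 4, 3 and 0 there and 11 without C45 replicate 1, and the p53 rises 1, 0, 1 and 2 there and 8 without either C45 library. By edgeR 1197 genes rose and 813 fell. The total of 2010 was 649 without wild-type replicate 2, 692 without C5 replicate 1, 520 without C5 replicate 2, 3429 without C45 replicate 1 and 3321 without C45 replicate 2, and the fallen were 535 without wild-type replicate 1. Correction for GC content and length gave 1338 and 1770 in place of 1197 and 813 and moved the median log2 difference of all genes from 0.02 to -0.08.

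In line C45 BNIP3 (495 CPM, mean of n = 2), PGK1 (log2 1.96) and SOX1 (log2 4.98) rose against wild type, and SLC7A11 and COL1A1 fell (log2 -3.73 and -2.31). TYW1 was 6.56-fold lower (adjusted p = 0.0020). Here 18 of 24 hypoxia and glycolysis genes and 15 of 25 p53 targets rose (19 and 15 adjusted over the list alone), and 10 of 13 mitochondrially encoded genes fell (12 adjusted over the list alone). Camera gave adjusted p = 3.68e-10, 1.63e-05 and 5.33e-09, and with an estimated correlation adjusted p = 0.354, 0.509 and 0.493. The p53 rises were 9 without either wild-type replicate, and SOX1 was at log2 7.10 and 4.16 without replicates 1 and 2. By edgeR 2199 genes rose and 1817 fell. The total of 4016 was 1900 without wild-type replicate 2 and 2459 without C45 replicate 2, and the fallen were 1149 without wild-type replicate 1 and 2772 with correction for GC content and length.

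Changes called in both lines numbered 1135 higher and 750 lower, with 0 in opposite directions, among them LHX1, SOX1, HES4, TEK, CBR1 and TYW1. They made up 94.8% of the rises and 92.3% of the falls called in C5. Independent lists of these sizes would share 137 and 76.7 genes. In 40 simulations of unchanged groups against the same wild-type libraries at most 2 genes were called in either line, so that their overlap of 0 in each direction gives no scale for these numbers. The log2 fold changes of the lines correlated at r = 0.874 across genes (0.506 simulated), had a covariance of 1.55 (0.143 simulated, a difference of 1.41) and shared their sign in 87.2% of genes (66.7% simulated). The wild-type pair cannot be split into parts of 2 libraries, so part of the excess may come from the shared controls. The shared calls were 426 higher and 206 lower without wild-type replicate 2, 498 and 184 without C5 replicate 1, and 377 and 136 without C5 replicate 2, and the lower ones were 496 without wild-type replicate 1 and 1379 without C45 replicate 1. With correction for GC content and length they were 1268 higher and 1627 lower.

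**Figure D4:**
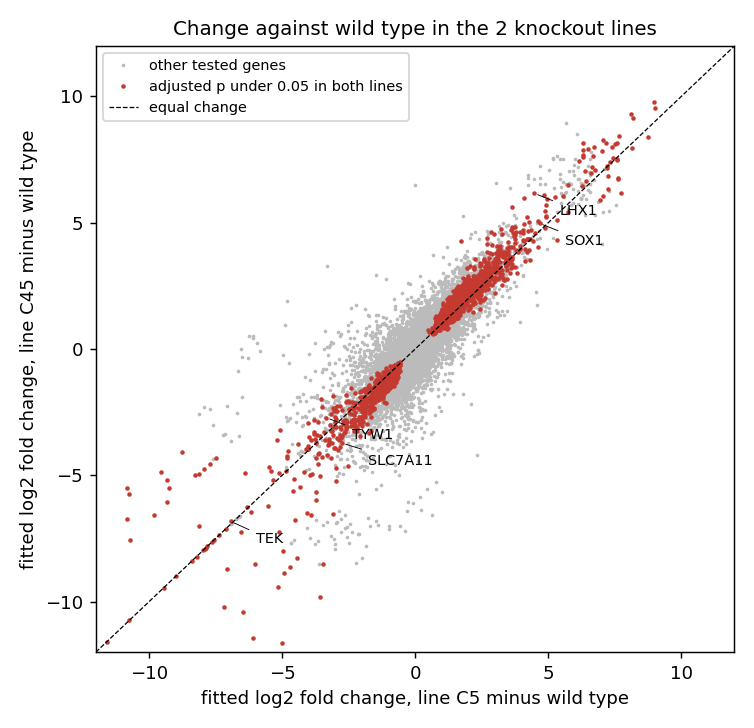
Fitted log2 fold change against wild type of each tested gene in line C5 (horizontal axis) and line C45 (vertical axis), with genes called in both lines in red. Most red points follow the line of equal change (r = 0.874 over all genes), and those far from it below -5 have no or few counts in a knockout line, where the fitted value depends on the prior count.

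The knockout lines did not differ from each other at any gene by edgeR. In C45 minus C5 the p53 targets GDF15 (6.47 and 37.1 CPM, means of n = 2 in C5 and C45; log2 2.52, SE 0.43), CDKN1A (15.2 and 48.8 CPM; log2 1.69, SE 0.33) and BBC3 (31.5 and 63.9 CPM; log2 1.02, SE 0.27) stood higher in C45 without passing (adjusted p = 0.448, 0.808 and 1.00). Adjusted over the list of 25 p53 targets alone, 3 passed as higher in C45 and 0 as lower. TYW1 had a log2 difference of 0.62 (SE 0.35). The count was 0 higher and 0 lower, with 560 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.283. DESeq2 called 9 and 5, limma voom 0 and 0, and edgeR without a low-count filter 26 and 10.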

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

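The tests of gene lists in this part were planned. The search for outlying libraries, and its count without series at 0, were not part of the design fixed beforehand. No explanation was tested for any value in this part. Among the 4 knockout libraries 13 of 186 series of values (6.99%, where chance gives about 5%) had 1 library far from the other 3, and in 11 of these it was C45 replicate 2. In 4 of the 13 the other 3 libraries had 0 counts, so that any count stands apart. Without the series with 0 in 3 or 4 libraries 9 of 180 (5.0%) remained, 7 of them in C45 replicate 2. HES4 was lower in C5 replicate 2 (3.45 CPM, others 5.81 to 6.28). ZNF248 (0.0503 CPM), HDX (0.101), ZNF736 (0.201) and ZNF37A (0.252) had counts in C45 replicate 2 and 0 in the others. In the same library PUS1 (37.2 CPM, others 51.5 to 53.6) and GARS1 (129 CPM, others 172 to 180) were lower. There BNIP3 (552 CPM, others 431 to 442), HMGB2 (525 CPM, others 390 to 409), SP8 (187 CPM, others 136 to 143), KCTD7 (34.4 CPM, others 16.9 to 17.5) and HHEX (11.1 CPM, others 8.04 to 8.55) were higher. C45 replicate 1 had a count in 23723 genes and the others in 25034 to 25216.

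Between the lines (C45 minus C5), 13 gene lists differed by camera at the preset correlation, and none held with an estimated correlation (lowest adjusted p = 0.651) or by fry (lowest adjusted p = 0.800). The median log2 difference was higher in C45 for p53 targets (0.59), cholesterol synthesis (0.38), mitosis (0.20), FGF and ERK targets (0.18), hypoxia and glycolysis (0.18), ribosomal proteins (0.15) and the nuclear-encoded respiratory chain (0.11). It was lower in C45 for pluripotency RNAs linked to HERV-H (-0.51), mitochondrially encoded genes (-0.27), DNA replication (-0.20), aminoacyl-tRNA synthetases (-0.12), other tRNA modification (-0.10) and ZNF-named genes (-0.076). These medians depended on single libraries. Without C45 replicate 2 those of DNA replication and the synthetases turned to 0.04 and 0.05, and the others moved to 0.25 (p53 targets), 0.17 (cholesterol synthesis), 0.042 (mitosis), 0.11 (FGF and ERK targets), 0.067 (hypoxia and glycolysis), 0.17 (respiratory chain), -0.50 (mitochondrially encoded) and -0.12 (ZNF-named). Without C45 replicate 1 they were -0.51 (DNA replication), -0.25 (synthetases and other tRNA modification), 0.29 (FGF and ERK targets), 0.32 (hypoxia and glycolysis), 0.063 (respiratory chain), -0.17 (mitochondrially encoded) and -0.13 (ZNF-named). Without C5 replicates 1 and 2 the FGF and ERK median was 0.087 and 0.30 and that of the respiratory chain 0.20 and 0.051, the synthetase median was -0.082 without replicate 1, and the median of other tRNA modification was -0.20 without replicate 2.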

How the results depend on the processing

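The correction for GC content and length and the phenylalanine tRNA list without TYW1 were chosen after the result was seen. TYW1 stayed lower and called in each alternative fitted to the mean of both lines (log2 -2.86 to -3.31), and none of 179 other named genes, or of the 175 tested at a mean of at least 1 CPM, changed a called sign there. Single genes were not followed at the 2-fold minimum or with only the 4 libraries compared. The calls of 44 were lost without wild-type replicate 2, of 29 without C5 replicate 2, of 27 without wild-type replicate 1, of 15 without C5 replicate 1 and of 49 in a test against a 1.5-fold change. The fold of 30 moved by more than 1.5 times without wild-type replicate 1, of 27 without wild-type replicate 2, of 7, 6 and 3 without C45 replicate 1, C45 replicate 2 and C5 replicate 1, of 16 by limma voom and also with line as a random block, of 7 with 2 genotype groups and of 1 with correction for GC content and length. That correction also raised the falls to 16 in other tRNA modification, 105 in ZNF-named genes and 4 in iron-sulfur cluster assembly, and the rises to 4 in interferon and RNA sensing and 3 in mitosis. Of 16 lists called by camera at the preset correlation none held with an estimated correlation and 8 held by fry, which called 4 others. For the hypoxia list the unadjusted camera p went from 6.88e-12 to 0.00784, though its estimated correlation of 0.0187 lay near the preset 0.01. For the fibroblast list, with an estimated correlation of -0.092, it went from 0.000678 to 0.0390. Failing that form of camera thus does not show that a list depends on the correlation of its genes. The cause of the following differences was not tested, except that a minimum fold change removes calls by its construction. Other settings gave, where a count moved by more than 1.5 times: DESeq2, 1373 lower in C5, 9 higher and 5 lower in C45 against C5, and 1263 lower in both lines; no low-count filter, 1951 higher and 1393 lower in C5, 26 and 10 in C45 against C5, and 1789 and 1254 in both lines. With only the 4 libraries compared, 1650 were lower in C5 and 1181 in C45. With the line as a random block (consensus correlation -0.36), 4131 were higher and 3984 lower in knockout. At a 2-fold minimum 1168 were lower in knockout, 1189 in C45 and 488 in both lines. Against a 1.5-fold change 919 were higher and 731 lower in knockout, 405 and 214 in C5, 918 and 605 in C45, and 392 and 187 in both lines. With correction for GC content and length 3292 were lower in knockout, 1770 in C5, 2772 in C45 and 1627 in both lines. Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, gave 997 to 2795 higher and 927 to 3228 lower in knockout, 382 to 1788 and 138 to 1715 in C5, 1046 to 2415 and 854 to 2513 in C45, 377 to 1364 and 136 to 1379 in both lines, and 0 in C45 against C5. DESeq2 size factors, total counts, limma voom and a mean of at least 1 CPM kept every one of these counts within 1.5 times. The fit with 2 genotype groups was run only for knockout against wild type, where it gave 2669 higher and 2323 lower, also within 1.5 times. At these depths, with 2 libraries per group, 39.8% of 2-fold changes in genes above 1 CPM were recovered in simulation. Only 200 genes were changed there, which makes the adjusted threshold stricter than in the data, so recovery in the data may be higher. Depth was not varied there, and counting error at 10 CPM (4.98% to 5.83%) lay below the biological coefficient of variation (26.3%).

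No label says that replicate numbers mark a shared culture or day, though the library codes run through replicate 1 of all groups before replicate 2. Deviations of libraries with the same number correlated at 0.11 (wild type and C5), 0.07 (wild type and C45) and 0.22 (C5 and C45), not all over 0.1, so the numbers were not taken as pairs. With a replicate block 5301 genes were called in knockout, 2821 in C5, 4856 in C45 and 0 in C45 against C5, with TYW1 at log2 -3.09. Of 179 other named genes 1 changed its call in that fit: APOA1 missed the threshold (log2 -3.07, adjusted p = 0.0503).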

Other observations

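Every explanatory test in this part was chosen only after the result was seen, while the gene lists were planned. Targets of FGF and ERK signalling rose in knockout against wild type, 8 of 16 with none lower (10 adjusted over the list alone). The feedback inhibitors DUSP6 and SPRY1 rose 2.61-fold and 2.23-fold, ETV5 2.7-fold and IER3 4.58-fold (camera adjusted p = 1.82e-05; adjusted p = 0.522 with an estimated correlation). Of 20 extracellular matrix and integrin genes 10 rose and 2 fell (also 10 and 2 adjusted over the list alone), with COL6A1 3.63-fold, COL6A2 2.66-fold and NID1 2.14-fold higher. ITGA6, a laminin receptor subunit, fell 2.55-fold, and so did ITGA1, named after its values were seen (camera adjusted p = 0.00298; adjusted p = 0.530 with an estimated correlation; the rises were 4 without wild-type replicate 2). Among 7 BMP targets ID2 (6.37-fold), SMAD6 and SMAD7 rose and ID1 and ID3 fell 2.40-fold and 2.00-fold (also 3 and 2 adjusted over the list alone; camera adjusted p = 0.348). SMAD7 and ID3 missed the threshold without wild-type replicate 2 (adjusted p = 0.118 and 0.100). Among 13 Notch genes 5 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0671). The ligands DLL1, DLL3 and JAG1 rose 7.02-fold, 4.86-fold and 2.87-fold and HES1 2.94-fold. JAG2 rose and HEYL and LFNG fell, all named after their values were seen, and the falls were 0 without wild-type replicate 2 and 1 without wild-type replicate 1, either C5 library or C45 replicate 2 and with total counts (HEYL at adjusted p = 0.0522). JAG2 missed the threshold without wild-type replicate 2 (0.206), C5 replicate 1 (0.0601) or C45 replicate 1 (0.0599) and with correction for GC content and length (0.0628), and DLL1 was at log2 4.45 and 2.03 in place of 2.81 without wild-type replicates 1 and 2. Of 15 WNT targets NKD2, RNF43, NOTUM and SP8 rose 2.76-fold to 7.69-fold and LEF1, named after its values were seen, fell (also 4 and 1 adjusted over the list alone; camera adjusted p = 0.103). LEF1 was the only fall, and the falls were 0 when any library but C45 replicate 1 was left out; NOTUM missed the threshold without wild-type replicate 2 (log2 2.18 in place of 2.94, adjusted p = 0.11), where SP8 was at log2 1.41 in place of 2.25, and without wild-type replicate 1 NOTUM, SP8 and RNF43 were at log2 4.69, 4.23 and 3.36. Of 11 Nodal and TGF-beta genes 3 fell, including TDGF1 and CER1, and 2 rose, including SMAD7 (also 3 and 2 adjusted over the list alone; camera adjusted p = 0.901). TDGF1 missed the threshold without wild-type replicate 2 (adjusted p = 0.0511) and CER1 without wild-type replicate 1 (0.423), C5 replicate 2 (0.0967) or C45 replicate 2 (0.0531), and the rises were 1 without wild-type replicate 2 or either C45 library.

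Imprinted genes rose more often than they fell, 6 and 1 of 19 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0183; adjusted p = 0.522 with an estimated correlation). CDKN1C, a cell cycle inhibitor, rose 5.26-fold and PEG3 fell 120-fold, from 5.04 ± 6.60 CPM in wild type. The rises were 1 without wild-type replicate 2 and 3 without C5 replicate 2, and PEG3 missed the threshold without wild-type replicate 2 (log2 -3.17 in place of -6.90, adjusted p = 0.226) and by limma voom (log2 -5.30, 0.0746). PEG3 was at log2 -7.89 without wild-type replicate 1 and -8.58 without C45 replicate 1, and CDKN1C at 3.22 in place of 2.40 without wild-type replicate 1. Of 9 NF-kB and inflammation genes ICAM1 (4.19-fold), NFKB2 (2.54-fold) and IER3 rose and RELB fell 2.31-fold (4 and 1 adjusted over the list alone; camera adjusted p = 0.0765; RELB at adjusted p = 0.185 without wild-type replicate 2 and 0.0834 without C5 replicate 2). Of 21 interferon and RNA-sensing genes IFITM1 (3.16-fold) and DDX60 rose and MX1 (9.69-fold), IFI6 and, named after its values were seen, TLR3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.828). The rises were 1 without wild-type replicate 1. The falls were 1 without either wild-type replicate or C5 replicate 2, with MX1 at adjusted p = 0.0574 without wild-type replicate 2 (log2 -3.93 in place of -3.28 without C45 replicate 1) and TLR3 at 0.149 with 2 genotype groups, and DDX60 was at 0.0588 and 0.0851 without wild-type replicates 1 and 2. Of 16 apoptosis genes BMF (3.87-fold), BBC3 (2.67-fold) and, named after its values were seen, PMAIP1 rose and BCL2L1 and BID fell 1.91-fold and 1.79-fold (3 and 3 adjusted over the list alone; camera adjusted p = 0.823), the falls being 0 without wild-type replicate 1 or C5 replicate 2 and 1 without wild-type replicate 2. Of 21 cholesterol synthesis genes 4 fell, including ACAT2, DHCR7 and LSS, and SC5D, named after its values were seen, rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.324), the falls being 1 without wild-type replicate 1 or C5 replicate 2 and 2 without C5 replicate 1. The rises there were 0 without wild-type replicate 2, either C5 library or C45 replicate 2 and 4 without C45 replicate 1. Of 19 genes of iron-sulfur cluster assembly 2 fell, including NUBP1 (2.02-fold; also 2 adjusted over the list alone; camera adjusted p = 0.22), 1 fell without wild-type replicate 2 or C5 replicate 2 and 5 without C45 replicate 1, and NUBP1 was also at adjusted p = 0.0742 without wild-type replicate 1. Of 54 clustered protocadherins PCDHA3, PCDHB16 and, named after their values were seen, PCDHB13 and PCDHGB6 rose and PCDHB5 and PCDHGA11 fell (0 and 2 adjusted over the list alone; camera adjusted p = 0.2), the rises being 0 without wild-type replicate 2 or either C5 library. PCDHB5 missed the threshold with 2 genotype groups (log2 -1.36, adjusted p = 0.139) and was at log2 -1.20 in place of -1.83 without wild-type replicate 1. Of 19 genes of 20q11.21, a segment often gained in cultured stem cells, DNMT3B, ID1, BCL2L1, HM13 and PLAGL2 fell and 3 rose, including DUSP15 and NOL4L (also 5 and 3 adjusted over the list alone; camera adjusted p = 0.27), PLAGL2, DUSP15 and NOL4L being named after their values were seen. These rises were 1 without either wild-type replicate or either C5 library and 5 without C45 replicate 2, and the falls were 3 without either wild-type replicate or C5 replicate 2. DUSP15 also missed the threshold by limma voom (adjusted p = 0.0607) and PLAGL2 with total counts (0.0561). The median, mean and camera direction of a list differed in sign for interferon and RNA sensing (0.16, -0.13, higher), Nodal and TGF-beta (0.06, -0.17, lower) and trophoblast and amnion (-0.19, 0.25, higher). These medians depended on single libraries: with 1 library left out the first ran from -0.01 (wild-type replicate 2) to 0.18 (wild-type replicate 1), the second from -0.34 (wild-type replicate 2) to 0.50 (wild-type replicate 1), lying below 0 also without either C45 library, and the third, over the same 5 genes, from -0.36 (wild-type replicate 2) to 0.59 (wild-type replicate 1).

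Both knockout lines differed from wild type in 2010 (C5) and 4016 (C45) genes and at no gene from each other by edgeR. On differences of mean log2 CPM (not the fitted fold changes, whose covariance was 1.55), shared wild-type libraries alone would give a covariance of 0.170 between the lines. The observed one was 1.08 (lower bound 1.045 over 1000 bootstrap draws of genes). That bound treats genes as independent and leaves out the spread between libraries. The value of 0.170 rests on a single wild-type pair and has no interval. With correction for GC content and length 96.6% of the calls stayed called, which argues against such a trend as the whole cause. Loss of TYW1 and a history that the knockout lines share apart from wild type, such as editing, cloning or culture density, cannot be told apart, because there is only 1 wild-type line.

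The 56 genes at least 20-fold lower in knockout may have different causes. Of 107 nearest expressed neighbours 6 (5.61%, Clopper-Pearson interval 2.09% to 11.8%) were also at least 20-fold lower. This argues against deletions that span several expressed genes as the cause of most of the 56. These 6 form 3 adjacent pairs, ZNF736 and ZNF680 among them, where such deletions stay open: 3 of the 6 had no count in knockout and the others 5 to 9. The interval counts each pair from both sides. In all, 30 of the 107 neighbours were called lower, as were 2154 of all 19254 tested genes. The neighbours had a mean of at least 1 CPM in wild type and include these 6. The 19254 were not chosen by level, so the shares are not matched. The median log2 change of the neighbours was -0.22, and its cause was not tested. Fewer cells of every other type would lower all their markers alike; the mean log2 change was 1.02 for 11 mesendoderm genes and -1.12 for 8 fibroblast genes (two-sided exact permutation test over 75582 regroupings, p = 0.0402), but for the same genes p was 0.398 without wild-type replicate 2, 0.0585 without C5 replicate 1 and 0.0526 without C45 replicate 1, so this too stays open. The mesendoderm and fibroblast means were 0.71 and -0.40 without wild-type replicate 2, and 1.71 and -1.34 without wild-type replicate 1. Both lists were picked for this test after their values were seen, which favours a low p. The permutation also treats genes as independent and leaves out the spread between libraries. Deletions of single genes, a change in fibroblast-like cells alone, silencing carried through cloning and an effect of TYW1 loss were not tested.

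Wild-type replicate 1 lay between wild-type replicate 2 and the knockout libraries on the first principal component, and replicate 1 minus replicate 2 had a median log2 difference of 0.22 over the 2336 genes that rose in knockout and -0.039 over the 2154 that fell. Over the 33 called genes with at least 5 CPM in replicate 2 and more than 20-fold less in knockout, replicate 1 had a median of 54.2% of the level in replicate 2 (54.8% over 27 genes chosen on the mean of the pair). Knockout cells mixed into replicate 1 could give these values, but would bring all genes at about 1 share: the 33 genes need a median share of 47.0%, while the share needed ran from 4.78% (10th percentile) to 45.7% (90th percentile) over 67 genes at 10 CPM or more in each knockout library and more than 10-fold lower in replicate 2, and TYW1 was not lower there (38.6 against 34.3 CPM). Loss of a copy of distal 18q in all cells of replicate 2 would lower its genes by about 1 log2 unit. The median over 29 genes was only -0.25 (interval -0.78 to -0.07), with 18 of them within 0.5 of 0. Loss in part of the cells would lower them less and stays open as a small shared shift, because the interval lies below 0. By itself it would not lower any gene by more than 1 log2 unit, while 7 of the 29 were lower by more than that. The segment was also chosen on these data, as it starts at DOK6, itself lower in replicate 2. Differences in culture state between the wild-type libraries stay open and were not tested.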
